A study of Mus musculus with 7 samples.

How the data were processed

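RNA from 7 mouse cell cultures was hybridised to 7 Affymetrix arrays. Per the labels' protocols, total RNA was extracted with Trizol and 100 ng was turned into biotin-labelled sense target with the Affymetrix whole transcript assay. The deposited values are log2 expression per probe set, which the authors made with RMA and Partek, per the submitters' processing notes. The versions, the probe set definitions and the background settings are not given in the sources used here. The deposited log2 values had medians between 4.97 and 5.03, minima between 0.86 and 1.01 and maxima between 13.96 and 14.04 on the 7 arrays, and they were used as deposited, with no further normalization or filter. No signal over background is given with them, so that low values are not separated from background here.

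The table held 28853 probe sets. The annotation table of the array named 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 5443 were not in it and stayed unnamed. Of the probe sets with 1 symbol 21698 matched a gene ID of the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Genes were tested through probe sets with 1 symbol, and of several probe sets for a gene (999 genes) the one with the highest mean over all arrays was kept, which left 19938 genes. No coordinates are given, because the build behind the array's annotation is not given in the sources used here.

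Groups were taken from the labels' titles and growth conditions: MEFs in FBS (1 array), MEFs in iCD1 (1), iPS lines O4-1, O4-2 and O4-4 in KSR (3), iPS line O4-1 in 2i (1) and ES cells in 2i (1). Other label fields differ from these. The description of every sample speaks of iPS cells shortly after infection, the source of the ES sample is given as fibroblasts, and the source of the iPS samples names iCD1 where titles and growth conditions name KSR or 2i. All pairs of arrays held different values. Where the labels do not say whether cultures were separate, p-values of single genes measure only the spread between the 3 KSR lines. No batch or date was found in the labels.

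Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in 1 fit of the 5 groups, two-sided, with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The 3 KSR lines gave the 2 residual degrees of freedom, to which limma's prior added 1.62 at a prior SD of 0.13, so that a group of 1 array was assumed to vary like the KSR lines. KSR iPS lines were tested against the mean of both MEF arrays, and iPS cells in 2i and ES cells in 2i were each tested against the KSR lines. MEFs in iCD1 against FBS, ES against iPS cells in 2i, and line O4-1 in both media compare 1 array with 1 and have no test. For these, and for pairs of KSR lines, genes differing 2-fold or more were counted. All errors after log2 differences are standard errors from limma.

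The study of gene groups used 35 lists with 629 entries, of which 55 had no probe set used here and 9 were found through a synonym. Lists were tested with limma's camera at its preset correlation between genes and Benjamini-Hochberg adjustment over the 35 lists, and again with an estimated correlation. At the preset correlation camera sets the members of a list against all other genes. Its p-values then measure the spread between genes, not between cultures, and for a group of 1 array they describe that array. The estimated form rests on the 2 residual degrees of freedom of the fit, so its p-values stay high for almost any list. The DNA methylation list, with an estimated correlation of -0.06, had an adjusted p of 0.464 there for iPS lines against MEFs (limma's camera). Other lists had high estimates, themselves rough with 2 degrees of freedom. They were 0.65 for the cholesterol and the formative and primed lists, 0.54 for p53, 0.53 for naive, 0.47 for glycolysis and 0.91 for sex-linked genes. The preset correlation is 1 small value for all lists, so p-values of such lists at the preset can be far too low. A call lost there does not show whether correlation between members made it. Beside camera the members past the threshold were counted, over all genes and adjusted over the list alone. In comparisons of 1 array with 1, the median of a list was set against 10000 random lists of its size, drawn from 20 bins of mean expression, as a percentile that describes these arrays only.

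Named genes followed a rule: in tested comparisons the 10 largest rises and the 10 largest falls among genes past the threshold whose difference had the same sign for every pair of arrays, in comparisons of 1 array with 1 the 10 largest differences each way among genes whose higher value was at or above the median of all tested genes on that array, and any member of a list. Predicted genes without an established symbol could be left out, which removed 1 gene from the rises of iPS cells over MEFs (a Gm gene) and 2 from the falls of ES cells against iPS cells in 2i (Rik genes). Line O4-1 in 2i against KSR was named by the same rule. Kit, Rarb, Crabp1, Crabp2, Dhrs3, Cyp26a1 and Cyp26b1 fall outside the rule and were chosen after their values were seen.

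Alternatives were a filter that keeps genes with a mean at or above the median, a trend or robust estimation in eBayes, quantile normalization again, centring each array on its median, every probe set with 1 symbol, leaving out each KSR line in turn, each MEF array alone, 3 cell types with both media together, and line O4-1 alone in both media. The scripts were tested on simulated data in which 50 genes per size were changed. For KSR iPS lines against MEFs (19938 genes) limma recovered 0%, 54%, 94% and 100% of changes of 0.5, 1, 2 and 4, with 10 false calls. For iPS cells in 2i it recovered 0%, 18%, 96% and 98% with 8 false calls, and for ES cells in 2i 0%, 16%, 92% and 98% with 7. For iPS cells in 2i against KSR alone, 35 lists were simulated, and the 1 that was moved was called and 0 others. The simulated errors were independent between genes and took limma's moderated spread as the true spread. The simulation is therefore kinder than the data, and its shares do not tell how many real changes were missed. In the data, Usp26 at -4.49 ± 0.53 in ES cells against KSR iPS lines did not pass. List members did not vary together in the simulation, so the 0 false list calls do not cover correlated lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probe sets with no symbol or several (7064) were left out of the comparisons of genes.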

Results

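Messenger RNA levels were measured on 7 Affymetrix expression arrays from mouse cells, each loaded with the RNA of 1 culture. Mouse embryonic fibroblasts (MEFs) gave 1 array in FBS medium and 1 array in the medium called iCD1. Induced pluripotent stem (iPS) cell lines O4-1, O4-2 and O4-4, made from fibroblasts infected with Oct4, gave 3 arrays in KSR medium, and line O4-1 gave 1 more array in N2B27 medium with 2i, a pair of inhibitors of MEK and GSK3. Embryonic stem (ES) cells of the OG2 background gave 1 array in the same 2i medium. Values are log2 expression, with array medians between 4.97 and 5.03, and differences are on the log2 scale. Only the iPS lines in KSR were replicated (n = 3 lines), so the spread of every difference tested for a single gene came from these lines. The small number of arrays limits the precision.

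The KSR iPS lines were compared with the MEFs to ask how cells made from fibroblasts with Oct4 differed from fibroblasts. Cell type and medium changed together, since no MEF array was in KSR. Pou5f1, which encodes Oct4, was at 3.40 and 4.04 in MEFs in FBS and in iCD1 and at 10.99, 10.99 and 10.61 in lines O4-1, O4-2 and O4-4. It rose by 7.15 ± 0.17 (SE, n = 3 lines against 2 MEF arrays; limma, adjusted p = 0.00659). Whether its probe set also reads RNA of the introduced Oct4 was not analysed here. The largest rise was that of Dppa5a, an RNA-binding protein gene of pluripotent cells, from a MEF mean of 3.52 to 12.49 ± 0.16 (SD, n = 3), a rise of 8.97 ± 0.13 (SE; limma, adjusted p = 0.00659). Tdgf1, which encodes the Nodal co-receptor Cripto, rose by 7.77 ± 0.20, Dppa2 by 6.13 ± 0.18 and Fbxo15 by 6.20 ± 0.54. The long non-coding RNA Lncenc1 rose by 6.45 ± 0.33, Fam169a by 5.81 ± 0.27, and the zinc finger genes Zfp980 and Zfp640, which belong to families with close copies, by 7.05 ± 0.32 and 6.33 ± 0.39. In the other direction, the small leucine-rich proteoglycan gene Ogn fell by 4.52 ± 0.63, its relative Aspn fell by 3.96 ± 0.26, the calpain family gene Capn6 fell by 4.31 ± 0.55 and the matrix glycoprotein gene Tnc fell by 4.18 ± 0.57. Tgfbi, which encodes a secreted matrix protein, fell by 4.14 ± 0.14, the annexin gene Anxa5 fell by 4.11 ± 0.28 and Igfbp5, an insulin-like growth factor binding protein gene, fell by 4.11 ± 0.26. The guidance ligand gene Sema3a fell by 4.09 ± 0.19, its receptor gene Nrp1 fell by 4.04 ± 0.10 and the mesenchymal homeobox gene Prrx1 fell by 3.94 ± 0.14. The adjusted p of the genes named so far ran from 0.00659 to 0.0198 (that of Ogn) in limma. In limma 5260 of 19938 genes passed an adjusted p of 0.05, 2415 higher and 2845 lower in the iPS lines, and 7779 had an unadjusted p under 0.05 against 997 expected by chance. Without line O4-1 or without line O4-2, limma called 0 genes, those named here included, although 5804 and 6924 had an unadjusted p under 0.05, and without line O4-4 it called 2776. With MEFs in FBS as the only fibroblast array limma called 2968 genes.

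**Figure D1:**
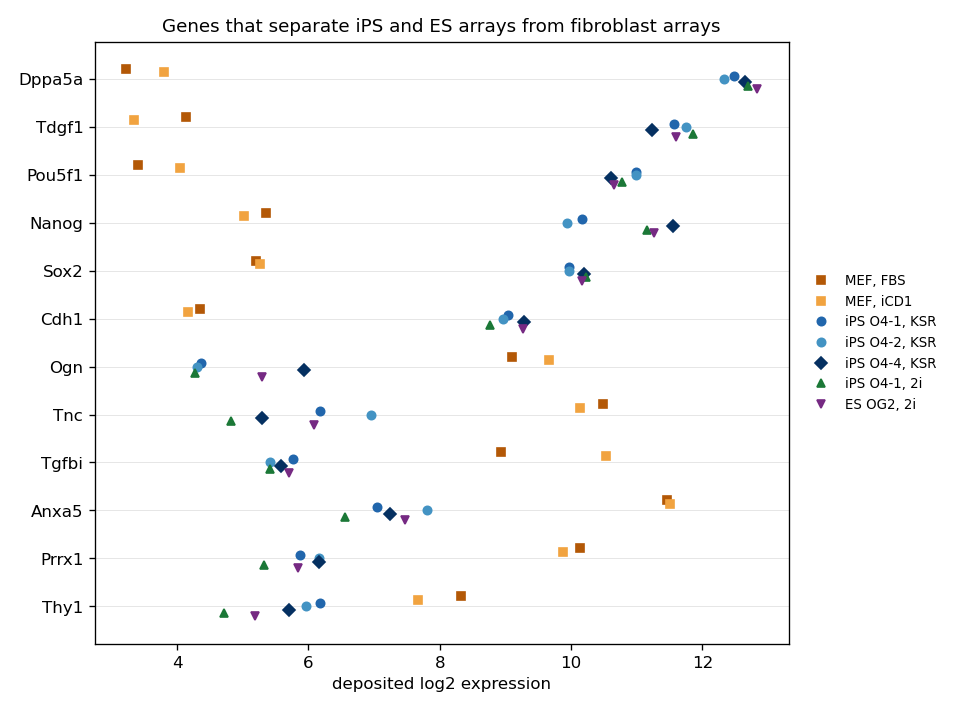
Deposited log2 expression (horizontal axis) of 12 genes, with 1 point per array and a colour and marker for each of the 7 arrays. The iPS and ES points of Pou5f1 lie between 10.61 and 10.99, and its MEF points are at 3.40 and 4.04.

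Genes of the pluripotency network rose together. All 23 measured members of the list lay higher in the iPS lines than in MEFs, with a median difference of 3.90, and 22 rose in limma over all genes and 23 when adjusted over the list alone (limma's camera, adjusted p = 7.72e-15, and adjusted p = 0.464 with an estimated correlation). Nanog, a core transcription factor of pluripotent cells, rose by 5.37 ± 0.60 (limma, adjusted p = 0.0135), and Sox2 and Sall4 each rose by 4.81 ± 0.12. Dnmt3l, a cofactor of the de novo DNA methyltransferases, was the member that did not pass over all genes, with 9.16, 8.99 and 5.54 in lines O4-1, O4-2 and O4-4. Of 17 naive pluripotency genes 12 rose over all genes and 16 when adjusted over the list alone, with a median of 2.76 (limma's camera, adjusted p = 1.97e-07, and adjusted p = 0.566 with an estimated correlation). Among them Nr0b1 rose by 5.58 ± 0.21, Zfp42 by 4.64 ± 0.46 and Esrrb, an orphan nuclear receptor gene, by 4.00 ± 0.49, whereas Klf4 was 0.87 ± 0.27 higher without passing (limma, adjusted p = 0.0993). Of 16 formative and primed pluripotency genes 4 rose, over all genes as well as adjusted over the list alone, with a median of 1.06 (limma's camera, adjusted p = 0.00373, and adjusted p = 0.748 with an estimated correlation). These were Dnmt3b, Nodal, Lefty2 and Cldn6, with rises of 3.57 ± 0.56, 2.66 ± 0.23, 3.23 ± 0.42 and 2.73 ± 0.56.

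Germline genes, chromatin regulators and cell cycle genes were also higher in the iPS lines. Of 22 germline genes 13 rose over all genes and 18 when adjusted over the list alone, with a median of 2.72 (limma's camera, adjusted p = 1.97e-07, and adjusted p = 0.515 with an estimated correlation). The RNA helicase gene Ddx4 rose by 3.01 ± 0.25, Sohlh2 by 3.83 ± 0.28 and Dazl by 4.32 ± 0.79. In the DNA methylation list 6 of 12 genes rose, also when adjusted over the list alone, with a median of 0.96 (limma's camera, adjusted p = 0.00885, and adjusted p = 0.464 with an estimated correlation), among them the dioxygenase gene Tet1 by 4.70 ± 0.20 and Hells by 2.60 ± 0.20. Of 24 epigenetic regulators 15 rose over all genes and 18 when adjusted over the list alone, with a median of 1.06 (limma's camera, adjusted p = 7.77e-06, and adjusted p = 0.464 with an estimated correlation). The Polycomb-associated genes Jarid2 and Cbx7 rose by 2.47 ± 0.11 and 2.45 ± 0.21. Of 24 cell cycle genes 15 rose over all genes, and adjusted over the list alone 17 rose and 1 fell, with a median of 0.89 (limma's camera, adjusted p = 1.60e-07, and adjusted p = 0.464 with an estimated correlation). The replication licensing genes Mcm2 and Cdt1 rose by 1.72 ± 0.11 and 1.83 ± 0.09, while the proliferation marker Mki67 was at -0.64 ± 0.15 (limma, adjusted p = 0.0591). Epithelial adhesion genes rose in 13 of 21 cases, over all genes as well as adjusted over the list alone, with a median of 1.49 (limma's camera, adjusted p = 9.41e-07, and adjusted p = 0.515 with an estimated correlation). E-cadherin (Cdh1) rose by 4.83 ± 0.14 and Epcam by 4.50 ± 0.26, and the keratin genes Krt8 and Krt18 did not pass, at 0.37 ± 0.29 and -0.19 ± 0.43. In the list of serine synthesis and the amino acid response 8 of 18 genes rose and 2 fell over all genes, and 9 rose and 2 fell when adjusted over the list alone, with a median of 0.67 (limma's camera, adjusted p = 0.0104, and adjusted p = 0.748 with an estimated correlation). Relative to the KSR mean the median of this list was -0.39 in MEFs in FBS and -0.78 in MEFs in iCD1, so the size of the rise depended on the MEF array. Asparagine synthetase (Asns) rose by 2.19 ± 0.33, and the cystine transporter gene Slc7a11 fell by 2.10 ± 0.46.

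Fibroblast genes fell. All 32 measured fibroblast and mesenchymal genes lay lower in the iPS lines, 29 fell in limma over all genes and 32 when adjusted over the list alone, and the median was -2.72 (limma's camera, adjusted p = 3.38e-16, and adjusted p = 0.464 with an estimated correlation). The growth factor receptor gene Pdgfra fell by 3.87 ± 0.24, the collagen gene Col1a2 fell by 3.12 ± 0.45 and the surface marker gene Thy1 fell by 2.06 ± 0.18. Of 19 serum response and contractile genes 14 fell over all genes and 18 when adjusted over the list alone, with a median of -2.07 (limma's camera, adjusted p = 3.36e-08, and adjusted p = 0.494 with an estimated correlation), among them smooth muscle actin (Acta2), which fell by 3.15 ± 0.47, and Thbs1, which fell by 3.28 ± 0.22. Of 14 TGF-beta targets 10 fell over all genes and 11 when adjusted over the list alone, with a median of -1.71 (limma's camera, adjusted p = 7.86e-06, and adjusted p = 0.464 with an estimated correlation). Of 30 Hox genes 24 fell over all genes and 27 when adjusted over the list alone, with a median of -1.12 (limma's camera, adjusted p = 1.41e-10, and adjusted p = 0.464 with an estimated correlation), and Hoxc5 and Hoxc8 had the largest falls of the list, where Hoxc5 fell by 2.63 ± 0.11 and Hoxc8 fell by 2.60 ± 0.16. Of 20 imprinted genes 9 fell and 1 rose, also when adjusted over the list alone, with a median of -1.63 (limma's camera, adjusted p = 0.000392, and adjusted p = 0.515 with an estimated correlation). The growth factor gene Igf2 fell by 3.53 ± 0.16, and Phlda2 was the member that rose, by 1.52 ± 0.33. Of 18 p53 targets and cell-cycle inhibitors 8 fell over all genes and 11 when adjusted over the list alone, with a median of -0.77 (limma's camera, adjusted p = 0.00218, and adjusted p = 0.748 with an estimated correlation), and the kinase inhibitor gene Cdkn2b fell by 1.77 ± 0.11. Of 20 cholesterol biosynthesis genes 5 fell, also when adjusted over the list alone, with a median of -0.35 (limma's camera, adjusted p = 0.00373, and adjusted p = 0.757 with an estimated correlation), and Hsd17b7 among them fell by 1.65 ± 0.21. Relative to the KSR mean the median of this list was 0.12 in MEFs in FBS and 0.60 in MEFs in iCD1. The fall thus rested mostly on the iCD1 array. In all, camera called 16 of 35 lists, 9 higher and 7 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. The estimated form has 2 degrees of freedom, so this loss does not show whether correlation between members made the calls. The lists for macrophages, endothelium, muscle, cartilage and bone, erythroid cells and keratinocytes were not called, with adjusted p of 0.0851, 0.511, 0.170, 0.287, 0.884 and 0.874 in limma's camera. The sex-linked list was drawn up from Xist and Y-linked genes, so a shared direction of its members does not tell of sex. It was not called either (limma's camera, adjusted p = 0.287). Of its 6 measured genes 2 rose and 1 fell over all genes, and 4 rose and 1 fell when adjusted over the list alone. Whether the MEF and iPS cultures differed in sex was not tested. Median, mean and camera differed in sign for 4 lists, 0 of them called.

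The fibroblast arrays were compared to see how MEFs in iCD1 differed from MEFs in FBS, without replicates and so without a test. The matrix proteoglycan gene Lum was at 9.94 in iCD1 against 6.06 in FBS (a difference of 3.87) and its relative Dcn at 9.61 against 6.78 (2.83). The matrix gene Dpt was 3.78 higher, Cadps 3.84, the carbonic anhydrase gene Car2 3.04, Capn6 2.93, Acss3 and Lix1 2.88 each, the retinol transporter gene Stra6 2.63 and the growth factor gene Bmp2 2.60. Lower in iCD1 were the growth factor gene Fgf7, at 5.71 against 9.35 (-3.64), and genes of the contractile apparatus, among them Actg2 (-2.81), the calponin gene Cnn1 (-2.72) and the transgelin gene Tagln (-2.62). The other large differences of this direction were those of Adamts5 (-2.72), Ankrd1 (-2.63), the activin antagonist gene Fst (-2.44), Sorbs2 (-2.43), Anxa8 (-2.35) and the chemokine gene Ppbp (-2.35). All 19 serum response and contractile genes were lower in iCD1, 9 of them 2-fold or more, and their median of -0.99 stood at percentile 0 of 10000 random lists matched on expression. All 20 cholesterol biosynthesis genes were higher, with a median of 0.48 at percentile 100. Wnt targets had a median of 0.26 at percentile 99.5, with Apcdd1 2.07, Axin2 1.94 and Nkd1 1.85 higher, and p53 targets and cell-cycle inhibitors had a median of 0.36 at percentile 100. Serine synthesis and amino acid response genes had a median of -0.55 at percentile 0, with Slc7a5 at -1.83, Mthfd2 at -1.81 and Asns at -1.80. The glycolysis and hypoxia list had a median of -0.37 at percentile 0, and the cell cycle list a median of -0.25 at percentile 0.33. The macrophage list had a median of 0.21 at percentile 99.53 with 7 of 13 members higher, among them the lysozyme gene Lyz2 at 6.83 against 4.99, and the interferon list a median of 0.21 at percentile 99.75. NRF2 and metallothionein genes had a median of 0.25 at percentile 99.77, TGF-beta targets of -0.35 at percentile 0.12 and primitive streak and endoderm genes of -0.30 at percentile 0.04. All 6 sex-linked genes were higher in iCD1, with a median of 0.38 at percentile 99.19. Whether the MEF cultures differed in cell types or in the embryos they came from was not tested. Fibroblast and mesenchymal genes went both ways, with 6 higher and 1 lower by 2-fold or more and a median of 0.02 at percentile 62.8. In total 339 genes were 2-fold or more higher and 199 lower in iCD1, 538 together. KSR iPS lines O4-1 and O4-2 differed in 122 genes, and the pairs with O4-4 in 310 and 564. Among genes with a mean at or above the median the counts were 183 and 119.

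**Figure D2:**
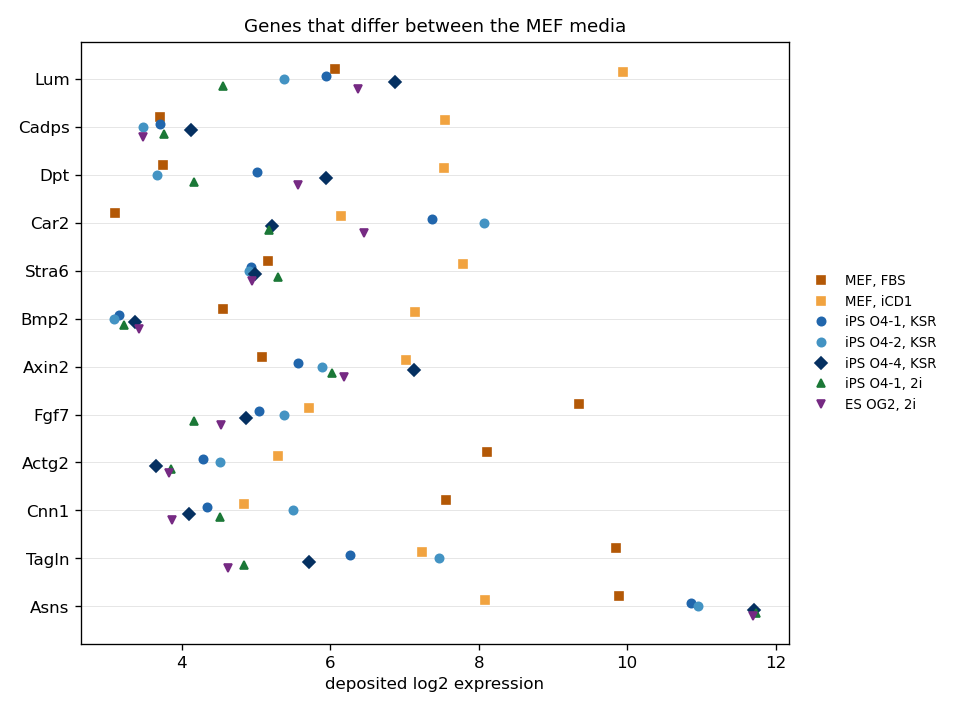
Deposited log2 expression (horizontal axis) of 12 genes that differed between MEFs in FBS and MEFs in iCD1, with 1 point per array and a colour and marker for each of the 7 arrays. Lum is at 6.06 in FBS and 9.94 in iCD1, and Fgf7 is at 9.35 in FBS and 5.71 in iCD1.

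The KSR iPS lines were compared with each other for the spread between replicates. The largest difference between O4-4 and either other line was that of Enpp3, at 3.81 in O4-4 and at 8.03 and 8.72 in O4-1 and O4-2. The naive factor gene Tfcp2l1 was at 9.68 in line O4-4 and at 7.37 and 6.70 in lines O4-1 and O4-2, and Tbx3 was at 8.87 against 7.28 and 6.74. Genes linked to the exit from the naive state were lower in O4-4, with Otx2 at 4.50 against 6.85 and 6.43 and the Nodal antagonist gene Lefty1 at 5.86 against 7.92 and 9.15. The naive list had a median difference of 0.57 between O4-4 and O4-1 and of 0.75 between O4-4 and O4-2, each at percentile 100 of 10000 random lists. The formative and primed list had medians of -0.85 and -1.35, each at percentile 0. MEK-ERK targets had medians of -0.40 and -0.62, each at percentile 0, with Dusp6, a phosphatase gene induced by ERK, at 5.75 in O4-4 and at 7.83 and 8.17 in O4-1 and O4-2. Fibroblast and mesenchymal genes had medians of 0.40 and 0.27, each at percentile 100, with the collagen gene Col1a1 at 10.32 in O4-4 and at 9.17 and 9.21. The glycolysis and hypoxia list was lower in O4-4, with medians of -0.20 and -0.49, and Bnip3 was at 6.42 against 8.01 and 8.83. The imprinted transcript Meg3 was at 6.90 in O4-4 and at 8.65 and 9.22 in the other lines. Lines O4-1 and O4-2 differed 2-fold or more in 122 genes, O4-1 and O4-4 in 310, and O4-2 and O4-4 in 564. Line O4-4 differed from the iPS array in 2i in 193 genes and from the ES array in 256.

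**Figure D3:**
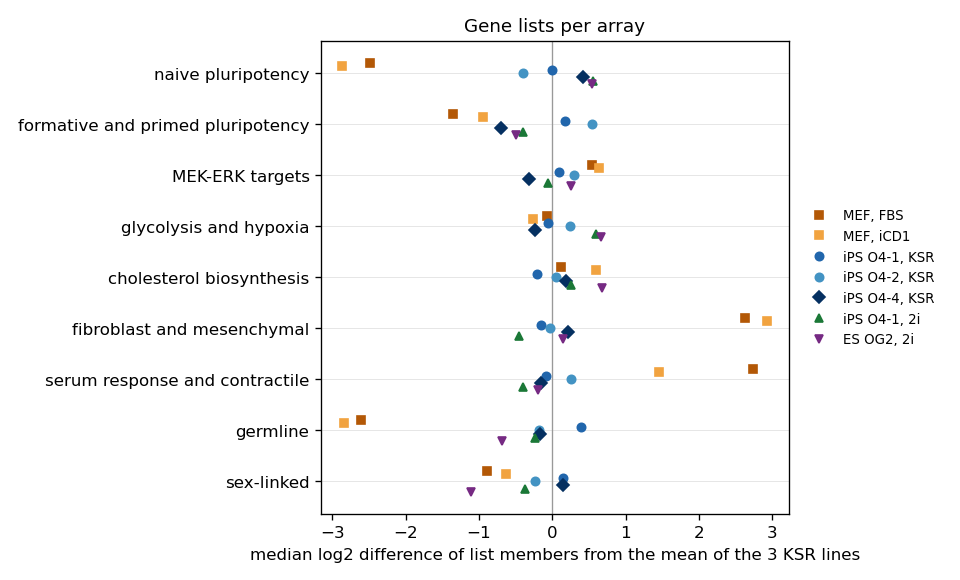
Median log2 difference of gene lists (horizontal axis) from the mean of the 3 KSR iPS lines, with 1 point per array and a colour and marker for each of the 7 arrays. The naive list is at 0.42 in line O4-4, 0.56 in iPS cells in 2i and 0.54 in ES cells in 2i, and the formative and primed list is at -0.70, -0.40 and -0.50.

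The iPS array in 2i was compared with the KSR lines to ask how iPS cells differed between the media. Pou5f1 was at 10.77 in 2i and at 10.86 ± 0.22 (SD, n = 3) in KSR. MEK-ERK targets had a median difference of -0.06 with 7 of 17 members higher in 2i. Wnt targets had a median of 0.01 with 7 of 14 higher, and over all lines neither list was called. Glycolysis and hypoxia genes lay higher in 2i in 20 of 22 cases, with a median of 0.59, and limma called 0 members over all genes and 0 adjusted over the list alone (limma's camera, adjusted p = 7.31e-05, and adjusted p = 0.880 with an estimated correlation). The phosphofructokinase gene Pfkp was at 9.13 in 2i and 7.78 ± 0.38 (SD, n = 3) in KSR, and Bnip3 was at 9.08 and 7.75 ± 1.22. Cholesterol biosynthesis genes lay higher in 19 of 20 cases, with a median of 0.26 (limma's camera, adjusted p = 0.00064, and adjusted p = 0.880 with an estimated correlation), and Stard4 was at 7.58 in 2i and 6.86 ± 0.04 in KSR. Fibroblast and mesenchymal genes lay lower in 29 of 32 cases, with a median of -0.46 (limma's camera, adjusted p = 1.63e-07, and adjusted p = 0.880 with an estimated correlation). Thy1 was at 4.71 in 2i and 5.94 ± 0.23 in KSR, and Mmp2, a matrix metalloproteinase gene, at 6.37 and 7.20 ± 0.09. Serum response and contractile genes lay lower in 18 of 19 cases, with a median of -0.40 (limma's camera, adjusted p = 5.80e-06, and adjusted p = 0.880 with an estimated correlation), and Acta2 was at 6.19 in 2i and 8.37 ± 0.68 in KSR. Imprinted genes lay lower in 16 of 20 cases with a median of -0.55, and inflammatory secreted genes in 14 of 17 with a median of -0.42 (limma's camera, adjusted p = 0.00423 and 0.0011, and adjusted p = 0.880 with an estimated correlation for both). The sex-linked list lay lower in 5 of 6 cases with a median of -0.37 (limma's camera, adjusted p = 0.0177, and adjusted p = 0.880 with an estimated correlation). In each of these lists 0 members passed, over all genes or adjusted over the list alone. The list p-values at the preset correlation set genes against genes and describe this 1 array in 2i. The naive list had a median of 0.56 and the formative and primed list of -0.40, and neither was called (limma's camera, adjusted p = 0.0856 and 0.108). With only members at or above the median expression the naive list was called, and so was the macrophage list with 2 members left (limma's camera, adjusted p = 0.000288 and 0.0309), 9 lists in all. Over all members and lines both had an adjusted p = 0.880 with an estimated correlation. In limma 0 of 19938 genes passed, the lowest adjusted p was 0.727, and 1339 genes had an unadjusted p under 0.05 where chance gives 997. By size alone 130 genes differed 2-fold or more, 36 higher and 94 lower in 2i. Without line O4-4 the count was 279, the naive and the formative and primed lists were called (limma's camera, adjusted p = 0.000389 and 6.71e-05, and over all lines adjusted p = 0.880 with an estimated correlation for both). So were epithelial adhesion, MEK-ERK targets and the p53 list (0.00348, 0.04005 and 0.00199), 11 lists in place of 7, while the sex-linked list was not (adjusted p = 0.114). Without line O4-1 the sex-linked list was not called either (limma's camera, adjusted p = 0.0912), and the interferon list was (adjusted p = 0.0394). Without line O4-2 the germline and serine lists were called as well (limma's camera, adjusted p = 0.02145 and 0.0469). All lists gained by leaving out a line were called at the preset correlation only, and over all lines none was called with an estimated correlation (limma's camera, lowest adjusted p = 0.880). Median, mean and camera differed in sign for 5 lists, 0 of them called.

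Within line O4-1, which was grown in both media, 286 genes differed 2-fold or more, 96 higher and 190 lower in 2i, with 1 array each and no test. The fatty acid desaturase genes Scd1 and Scd2 were 2.37 and 1.99 higher in 2i, and the naive factor genes Tfcp2l1 and Tbx3 were 1.74 and 1.63 higher. Ly75 was 2.27 higher, Elovl7 1.63, Lrrc34 1.62, Alpk3 1.59, and Lrrc31 and Cmtm7 1.58 each. Lower in 2i were Enpp3 (-3.22), the synaptonemal complex gene Sycp1 (-3.17), Cubn (-2.83), the interferon-inducible gene Irgm1 (-2.61), the carbonic anhydrase genes Car4 (-2.52) and Car2 (-2.20), Otx2 (-2.22), Dnmt3l (-2.10), the neurofilament gene Ina (-2.09) and Lefty1 (-2.06). The naive list had a median of 0.51 with 15 of 17 members higher, at percentile 100 of 10000 random lists, and the formative and primed list a median of -0.60 at percentile 0. Germline genes had a median of -0.68 at percentile 0, and 8 of 22 were 2-fold or more lower. Relative to the KSR mean this list was at 0.39 in O4-1 in KSR and at -0.24 in 2i, near -0.18 and -0.17 in O4-2 and O4-4 in KSR. O4-4 against O4-1, both in KSR, had a median of -0.46, also at percentile 0. The germline difference thus rests largely on a high O4-1 array in KSR and cannot be laid to the medium. Glycolysis and hypoxia genes had a median of 0.64 and cholesterol biosynthesis genes of 0.47, each at percentile 100, and fibroblast and contractile genes had medians of -0.31 and -0.42, each at percentile 0. MEK-ERK targets had a median of -0.14 at percentile 12.5. Among genes with a mean at or above the median 43 were 2-fold or more higher and 117 lower.

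ES cells in 2i were compared with the KSR iPS lines as a pluripotent reference, with cell source and medium changing together. List p-values at the preset correlation set genes against genes and describe this 1 ES array. The estimated correlations of the cholesterol, glycolysis and sex-linked lists were 0.65, 0.47 and 0.91, so their p-values at the preset can be far too low. All 20 cholesterol biosynthesis genes lay higher in ES cells, with a median of 0.68, and 0 passed over all genes and 2 when adjusted over the list alone (limma's camera, adjusted p = 9.69e-12, and adjusted p = 0.982 with an estimated correlation). Cyp51 was at 8.51 in ES cells and 7.56 ± 0.08 (SD, n = 3) in KSR iPS cells, and Stard4 at 7.83 and 6.86 ± 0.04. Glycolysis and hypoxia genes lay higher in 21 of 22 cases, with a median of 0.67 and 0 passing over all genes or adjusted over the list alone (limma's camera, adjusted p = 7.54e-07, and adjusted p = 0.982 with an estimated correlation), and Pfkp was at 9.16 in ES cells. TGF-beta targets lay higher in 10 of 14 cases with a median of 0.18, 0 over all genes and 2 when adjusted over the list alone (limma's camera, adjusted p = 0.0495, and adjusted p = 0.982 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, was at 6.43 against 4.72 ± 0.25 and Ccn2 at 9.37 against 7.84 ± 0.09. Germline genes lay lower in 19 of 22 cases with a median of -0.68, and 0 passed over all genes or adjusted over the list alone (limma's camera, adjusted p = 0.000826, and adjusted p = 0.982 with an estimated correlation). Slc25a31, a mitochondrial carrier gene of the germline, was at 3.41 in ES cells and 6.46 ± 0.61 in KSR iPS cells. All 6 sex-linked genes lay lower with a median of -1.11, 0 over all genes and 3 when adjusted over the list alone (limma's camera, adjusted p = 0.000608, and adjusted p = 0.982 with an estimated correlation). The Y-linked genes Kdm5d and Eif2s3y were at 3.38 and 6.41 in ES cells and at 5.77 ± 0.53 and 7.92 ± 0.24 in KSR iPS cells. MEK-ERK targets had a median of 0.26 with 12 of 17 members higher in ES cells. Wnt targets had a median of 0 with 7 of 14 higher, and over all lines neither list was called. The pluripotency network list was not called, with a median of -0.20 (limma's camera, adjusted p = 0.832). In limma 0 of 19938 genes passed, the lowest adjusted p was 0.571, and 1746 genes had an unadjusted p under 0.05 where chance gives 997. By size alone 320 genes differed 2-fold or more, 159 higher and 161 lower, 535 without line O4-4, and 212 among genes with a mean at or above the median. With only list members at or above the median expression camera called 7 lists in place of 5, adding the naive list and the macrophage list with 2 members left (limma's camera, adjusted p = 0.00566 and 0.00195, and over all members adjusted p = 0.982 with an estimated correlation for both). Without line O4-4 camera called 11 lists. It added the naive and the formative and primed lists (limma's camera, adjusted p = 0.000961 for both), fibroblast genes (0.0152), LIF-STAT3 targets (0.00946), DNA methylation (0.0351), early neural (0.0349) and imprinted genes (0.0388). These calls are at the preset correlation, and over all lines the same lists had an adjusted p = 0.982 with an estimated correlation. Without line O4-1 the interferon list was called (limma's camera, adjusted p = 0.0275, and over all lines adjusted p = 0.982 with an estimated correlation), and TGF-beta targets were not called without line O4-4 or without line O4-1 (limma's camera, adjusted p = 0.165 and 0.109). Median, mean and camera differed in sign for 5 lists, 0 of them called. With the arrays fitted as 3 cell types, which counts the KSR and 2i arrays of line O4-1 as independent and has only 1 ES array, limma called 1 gene, Ipp, at 7.06 in ES cells and at a mean of 5.06 in 4 iPS arrays (adjusted p = 0.0472).

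ES cells and iPS cells in the same 2i medium were compared to set cell sources side by side, with 1 array each and no test. Higher in ES cells were Id2 (2.23), the matrix genes Thbs1 (1.96), Lum (1.80), Efemp1 (1.77) and Thbs2 (1.75), and Ccn1 (1.74), a target of serum response. Dmgdh was 1.95 higher, Ipp 1.90, Pramel7 1.89 and the raft protein gene Rftn1 1.83. Lower in ES cells were Usp26, at 4.10 against 7.39 (-3.29), the Y-linked gene Zfy1, at 2.56 against 5.30 (-2.74), Efhc2 (-2.42), Ct55 (-2.29), Slc25a31 (-2.15), Scml2 (-1.95), Nxf3 (-1.74) and Rragb (-1.54), of which Usp26, Efhc2, Ct55, Scml2, Nxf3 and Rragb are X-linked in the mouse. Germline genes had a median of -0.38 and sex-linked genes of -0.68, each at percentile 0 of 10000 random lists. Fibroblast and mesenchymal genes had a median of 0.50 with 29 of 32 higher, contractile genes of 0.42, cholesterol biosynthesis genes of 0.35 and inflammatory secreted genes of 0.30, at percentiles 100, 100, 100 and 99.97. The pluripotency network list had a median of -0.07 at percentile 7.34, and the naive list of 0.11 at percentile 88.8. In total 134 genes were 2-fold or more higher and 61 lower in ES cells, 195 together. KSR lines O4-1 and O4-2 differed in 122 genes, and the pairs with O4-4 in 310 and 564. Among genes with a mean at or above the median the counts were 78 and 22.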

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

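The tests of explanations in this part were all chosen after the result was seen. Among 7064 probe sets without a single gene symbol, which the comparisons of genes leave out, limma called 146 between the KSR iPS lines and MEFs at an adjusted p of 0.05 within these probe sets, 102 higher and 44 lower in the iPS lines, and 1719 had an unadjusted p under 0.05. The largest rise was 7.07. They came up because a signal above the fibroblast arrays lay outside the genes compared. Of the 7064 probe sets 1621 carry several gene symbols and 5443 are not in the annotation, and no gene is named from them here.

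Line O4-4 in KSR lay nearer to the 2i arrays (193 genes 2-fold or more from iPS in 2i, 256 from ES) than to lines O4-1 and O4-2 (310 and 564). An exchange with the iPS array labelled 2i would, were the lines alike, put that array close to lines O4-1 and O4-2, which differed from each other in 122 genes. It differed from them in 286 and 464 and from ES cells in 2i in 195, but pairs of KSR lines spread from 122 to 564, so an exchange cannot be told apart from a difference of line O4-4 itself. Fibroblast RNA in the O4-4 culture was argued against as the whole cause, which would need nearly all genes higher in O4-4 to be higher in MEFs. Of 108 genes 2-fold higher in O4-4 than in both other lines 33.3% were 2-fold higher in MEFs. Genes outside the lists that mark MEFs had a median of 0.05 above the other lines. Over all genes, 1886 of 19938 were 2-fold higher in the MEF mean than in the KSR mean, which includes O4-4. The 33.3% was taken against lines O4-1 and O4-2 alone. The 108 genes were chosen for low values in these lines, a choice that favours genes higher in MEFs. The share over all genes is thus no matched baseline for the 33.3%. The fibroblast list was higher in O4-4 with medians of 0.40 and 0.27, so that fibroblast RNA as a part of the cause stays open. A culture of O4-4 in 2i in place of KSR may account for part of the pattern, and it cannot be told apart from a difference of the line itself. O4-4 minus O4-2 correlated across genes, which are not independent replicates, with O4-1 in 2i minus KSR at r = 0.27. O4-1 minus O4-2 in KSR correlated with ES minus iPS in 2i at -0.05. Neither of these last contrasts holds a change of medium, so that value is no baseline for the 0.27. The glycolysis and hypoxia list, higher in both 2i arrays, was at -0.23 in O4-4. MEK-ERK targets were at -0.32 in O4-4 and at -0.06 and 0.26 in the iPS and ES arrays in 2i. The line difference was not tested.

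Fibroblast and contractile genes were lower in the iPS array in 2i than in KSR, with medians of -0.46 and -0.40. Fewer fibroblasts, or feeder cells of that kind, in the 2i culture would also lower fibroblast genes outside the lists. Of 116 genes 8-fold or more higher in MEFs than in ES cells in 2i, 92.2% were lower in iPS cells in 2i than in the KSR mean, with a median of -0.51. Of all genes 47.1% were lower. The 116 genes were chosen for low values in an array in 2i, a choice that favours genes low in 2i in both cell sources. The 47.1% is thus no matched baseline, and fewer fibroblasts stays a hypothesis that the 92.2% does not decide. A lowering of these genes by the 2i medium cannot be told apart from it: in ES cells in 2i the fibroblast list had a median of 0.14, but ES cells are another cell source, and the 116 genes, at -0.28 there, were chosen for being low in that array, so that this value decides nothing. The most abundant fibroblast list genes in KSR, Fn1 and Vim, were at 10.33 and 9.62 in 2i against 10.14 and 9.73, but ES cells express them at 10.84 and 9.84, so that they exclude nothing.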

How the results depend on the processing

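The leave-one-out of gene lists and, within the comparison of line O4-1 in both media, the filter, normalization and probe set alternatives were added after the data were seen. The other alternatives, line O4-1 alone among them, and the lists were chosen before the data were examined. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers, and only line O4-1 is in both media. Leaving out 1 KSR line gave 0 to 2776 called genes between iPS lines and MEFs in place of 5260 (1 residual degree of freedom remains), 127 to 279 genes differing 2-fold or more for iPS cells in 2i in place of 130, and 277 to 535 for ES cells in place of 320. It gave 7 to 11 called lists for iPS cells in 2i in place of 7, and 5 to 11 for ES cells in place of 5, and all 16 lists for iPS lines against MEFs. With MEFs in FBS alone 2968 genes were called, 2931 of them among the 5260. With 3 cell types in 1 fit 1 gene was called for ES cells, and the cause was not tested. Line O4-1 alone gave 286 genes for 2i. With only genes at or above the median, so fewer genes, 212 genes differed for ES against KSR, 78 and 22 (higher and lower) for ES against iPS in 2i, 183 and 119 for the MEF media, and 43 and 117 for line O4-1. In these comparisons of 1 array with 1, leaving out dim members moved 22 list medians by more than their SD over the 3 KSR lines. With an estimated correlation 0, 0 and 0 lists were called in the tested comparisons, where 2, 0 and 0 had an unadjusted p under 0.05 in camera. That form rests on 2 degrees of freedom, so it cannot tell whether correlation between members made the other calls. Among called genes, with MEFs in FBS alone the differences of Cadps and Lix1 turned to 0.06 and 0.12, and with MEFs in iCD1 alone those of Ccn2 and Anxa8 turned to 0.35 and 0.46, since these genes differ between the MEF arrays. Genes that were not called turned too, Dpt to 1.13 and Dcn to 0.28 with MEFs in FBS alone. Trend, robust estimation, quantile normalization, centring and all probe sets kept every count within 1.5 times, with 5181 to 6036 called genes between iPS lines and MEFs. The values have no measure of signal over background, which leaves dim genes uncertain.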

Other observations

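The genes of this paragraph and the simulation of the next were chosen after the values were seen, and no gene here was tested. In MEFs in iCD1 against FBS the retinoic acid receptor gene Rarb was at 6.62 against 4.61, the binding protein genes Crabp1 and Crabp2 at 11.84 against 9.83 and 8.77 against 7.18, and the retinal reductase gene Dhrs3 at 9.06 against 6.63. The retinoic acid hydroxylase genes Cyp26a1 and Cyp26b1 were at 3.50 against 3.21 and at 5.52 against 5.50, and no list of retinoid genes was tested. The transferrin receptor gene Tfrc, of the housekeeping list, was at 6.19 against 8.46. The receptor gene Kit was at 9.56 in line O4-4, 7.48 in O4-1 and 6.98 in O4-2 in KSR, at 9.18 in ES cells in 2i, and 1.52 higher in 2i than in KSR within line O4-1.

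The differences of iPS cells in 2i and of ES cells in 2i from the same KSR lines correlated across genes at r = 0.52, where simulated unchanged groups against these lines gave 0.25, and genes are not independent replicates. The covariance was 0.0515 against 0.0138 simulated, a difference of 0.0376, and 67.5% of genes had the same sign against 58% simulated (100 simulations). The simulation holds no real effects and takes its spread from limma, and the KSR lines are too few to split, so whether part of the excess comes from the shared arrays was not tested.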
